A study of Mus musculus with 16 samples.

How the data were processed

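The files hold raw read counts per tRNA transcript, which the authors deposited as 1 table for the MEFs and 1 for the hearts; the counts are whole numbers and were not normalized. Per the labels' protocols, total RNA was extracted under mild acid, oxidised and beta-eliminated, a chemistry that marks charged tRNA ends, and libraries followed the mim-tRNAseq workflow on an Illumina NextSeq 500. Per the submitters' processing notes, cutadapt 3.5 and the mouse build mm39 were used; the aligner, the counter and the treatment of reads shared between near-identical tRNAs are not given in the sources used here. The tables hold 819 rows (MEF) and 821 rows (heart), with 22 mitochondrial tRNAs, 265 and 267 nuclear tRNAs and 532 rows named tRX in each; tRX rows took 26 to 193 counts per library. Some near-identical transcripts share a row in 1 table and not in the other, so the tables were tested separately. All 16 columns were matched to sample titles. The tables hold no counts per tRNA end, so the planned comparison of charging was not run.

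Groups came from the sample titles: MEF_Ctrl_1, MEF_Cl_1, MEF_Cl_2 and MEF_Cl_3 with 2 libraries each, and AAV9-GFP and AAV9-DdCBE hearts with 4 each. Titles do not explain Ctrl, Cl or the X labels (2X to 10X) and none of these was interpreted. Per the labels' protocols, the MEF replicates are cell passages and the hearts are separate mice. All 16 pairs of replicates within a group differed by more than sampling noise (chi-square per degree of freedom 93.9 to 1781), so no replicate was a copy of another of its group.

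Counts were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr by group with its minimum count of 10 and minimum total of 15, glmQLFit and glmQLFTest), with Benjamini-Hochberg adjustment over the transcripts tested and a threshold of 0.05. The filter left 201 transcripts in the MEFs (22 mitochondrial, 175 nuclear, 4 tRX) and 180 in the hearts (22 mitochondrial, 158 nuclear). The 8 MEF libraries entered 1 fit with the line as factor and the 8 hearts 1 fit with the treatment as factor. The SE of a log2 change was taken as its size divided by the square root of the F statistic. CPM values are TMM-scaled. Shares of counts were compared by exact two-sided permutation tests. In the heart comparison by X label, the AAV9-DdCBE hearts were split into 10X, 5X and 2X; this design was added after the comparison of 4 with 4 had called 0 transcripts. The exact test of the difference between strands was also chosen after the data were examined. With 1473330 to 4375975 counts per library, mt-tRNA-Ala had 359 to 19022 counts. 95% Wilson intervals for its share of mitochondrial tRNA counts were 0.380% to 0.467% in the library with the fewest and 1.03% to 1.06% in the library with the most, and cover counting error only.

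Named transcripts followed a rule fixed before the data were examined: mt-tRNA-Ala always, every other mitochondrial tRNA past the threshold, up to 8 nuclear transcripts that rose and 8 that fell with the smallest adjusted p, the 5 with the smallest p where fewer than 5 pass, and nuclear tRNA-Ala as a group. tRNA-Ala-TGC-5 and tRNA-Ala-AGC-2 in the mean of the Cl lines, and mt-tRNA-Glu and mt-tRNA-Asn, were chosen as examples after their values were seen. Lists fixed beforehand were tested with camera and fry in limma 3.58.1 on voom log-CPM (preset correlation 0.01, repeated with an estimated one): the mitochondrial tRNAs without Ala, those on its strand, those on the other strand, its neighbours, nuclear tRNA-Ala, nuclear tRNAs with A at the first anticodon position, nuclear tRNAs with a long variable arm, and 20 further nuclear amino acid families. In the mean of the Cl lines the camera adjusted p was 0.963 for the nuclear tRNAs with that first anticodon base and also 0.963 for those with a long variable arm, and 0.174 to 0.977 for the 20 families; fry, which asks only whether a list moves one way, passed for both mitochondrial lists that camera called and for 5 families, Asn, Cys, Gln, Glu and Trp. In the hearts camera and fry called 0 lists, and fry called 9 in the 10X hearts. Gene order around mt-tRNA-Ala came from a RefSeq table of GRCm38.p6, used for names and neighbours only.

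The pipeline was tested on simulated data with the real means, depths and dispersions and 40 transcripts changed by 2-fold or 4-fold. For the mean of the Cl lines (201 transcripts) 91.5% of 2-fold and 99.0% of 4-fold changes were recovered, with 4.75% of calls false. For AAV9-DdCBE against AAV9-GFP (180 transcripts) 63.0% and 93.0% were recovered, with 4.29% false. For 1 Cl line against Ctrl_1 the values were 88.0% and 98.5%, with 5.81% false. For the 10X hearts against AAV9-GFP they were 85.0% and 99.5%, with 5.14% false. The simulations changed as many transcripts up as down and held no other difference between libraries. In the data 97 of 201 transcripts passed for the mean of the Cl lines and 93 of 180 for the 10X hearts. In the latter rises reached 52.8-fold and the median log2 change was -0.23. The simulated shares of false calls therefore need not hold for these comparisons.

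Alternatives were DESeq2 1.42.0 size factors, library totals, nuclear counts or the other mitochondrial tRNAs as scaling, the DESeq2 Wald test, no filter, at least 100 counts in every library, only the lines compared, a replicate block, libraries summed per line, the X label as covariate or only 5X hearts, counts summed per anticodon, filtered transcripts as the denominator of shares, and leaving out each library. The split by X label, a covariate for a library axis and the MEF shares with lines as units were added after the data were examined. Scaled on the other mitochondrial tRNAs, the fit still covered all tested transcripts. Nuclear rows, offset by the mitochondrial share, thus entered the spread estimate and the adjustment there. Plots were drawn with matplotlib 3.10.9.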

Results

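tRNA abundance was measured by mim-tRNAseq, a sequencing method for full-length tRNA, in 16 mouse libraries from a study of base editing of a pathogenic mutation in the mitochondrial gene for tRNA-Ala. The first set held 8 libraries of mouse embryonic fibroblasts (MEFs), 2 each from 1 line named Ctrl_1 and 3 lines named Cl_1, Cl_2 and Cl_3. The second set held 8 hearts, 4 from mice given AAV9-GFP and 4 from mice given AAV9-DdCBE. AAV9 is a viral vector with strong delivery to the heart, GFP is a fluorescent control protein, and a DdCBE is a protein base editor that converts cytosine in mitochondrial DNA. Each library held 1473330 to 4375975 counts in the MEFs and 1540287 to 3037178 in the hearts. A transcript is named by amino acid, anticodon and a running number, so that tRNA-Cys-GCA-4 is 1 of several near-identical tRNAs with the GCA anticodon; mitochondrial tRNAs carry the prefix mt.

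In the MEFs, mt-tRNA-Ala, which carries alanine to the mitochondrial ribosome and whose gene is the subject of the series, was lower in all Cl lines than in Ctrl_1. Its level was 522 ± 93.1 CPM (counts scaled to library size; SD, n = 2) in Ctrl_1, against 143 ± 24.9 in Cl_1, 261 ± 37.6 in Cl_2 and 115 ± 15.97 in Cl_3 (SD, n = 2 each). The mean log2 change of the Cl lines was -1.68 (SE 0.16), a 3.21-fold lower level (edgeR quasi-likelihood test, adjusted p = 1.95e-04). The change was -1.87 in Cl_1 (SE 0.22, edgeR adjusted p = 0.00105), -1.003 in Cl_2 (SE 0.21, edgeR adjusted p = 0.00819) and -2.18 in Cl_3 (SE 0.22, edgeR adjusted p = 2.67e-04). The Cl lines also differed among themselves in mt-tRNA-Ala (edgeR F test over the lines, adjusted p = 0.0143), and Cl_2 was 0.87 above Cl_1 on the log2 scale (SE 0.21, edgeR adjusted p = 0.0338). Cl_3 lay 1.17 below Cl_2 (SE 0.22, edgeR adjusted p = 0.0551) and 0.30 below Cl_1 (SE 0.21, edgeR adjusted p = 0.326), each adjusted within its own comparison and neither past the threshold. Without replicate 1 of Cl_1 the difference of Cl_2 from Cl_1 was 0.66 (edgeR adjusted p = 0.169), and without replicate 2 of Cl_2 it was 0.72 (edgeR adjusted p = 0.167). Scaled on the other mitochondrial tRNAs, Cl_3 passed against Cl_2 (-1.09, edgeR adjusted p = 0.00107). Under that scaling Cl_2 also passed against Cl_1 (0.89, edgeR adjusted p = 9.89e-04), and Cl_3 against Cl_1 did not (-0.20, edgeR adjusted p = 0.646). The fit under that scaling kept the nuclear rows, so its adjusted p-values are not comparable with those of the main fit. The replicates were passages of a line, so all p-values of this paragraph from separate libraries measure the spread between passages. With the libraries of each line summed and 3 lines set against 1, the log2 change was -1.60 and missed the threshold (edgeR adjusted p = 0.105), and without replicate 1 of Cl_2 the change in that line was -0.84 (edgeR adjusted p = 0.0578).

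**Figure D1:**
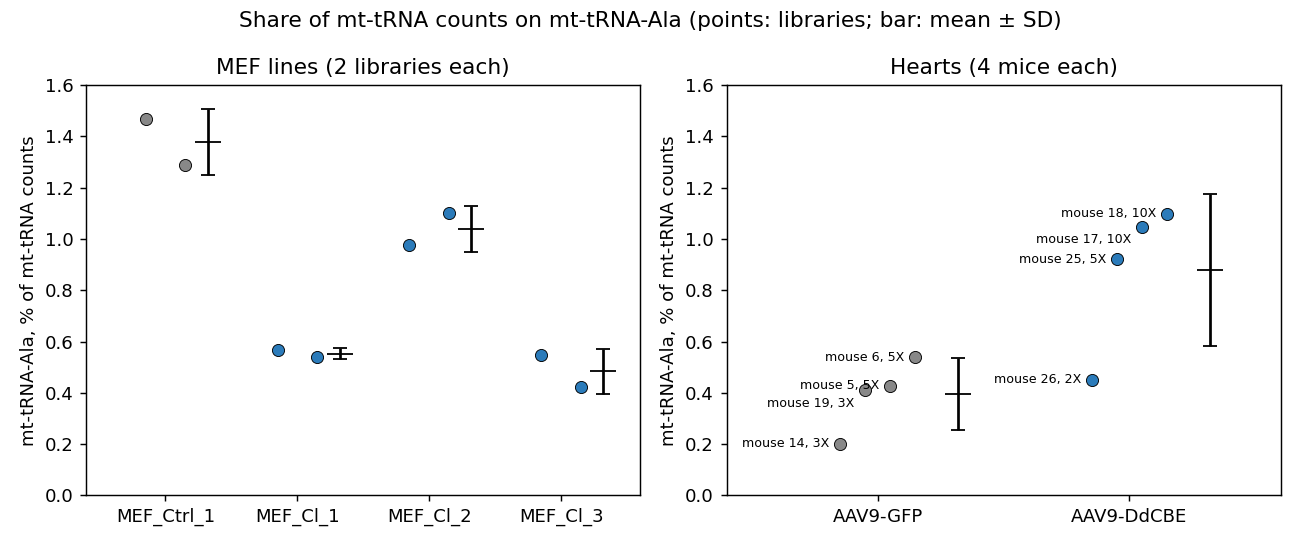
Share of mitochondrial tRNA counts that fell on mt-tRNA-Ala, in percent, for each MEF library (left) and each heart (right, with mouse number and X label); points are libraries and bars are means ± SD. All Cl libraries lie below both Ctrl_1 libraries, and the AAV9-DdCBE hearts average 0.879% against 0.394% in AAV9-GFP.

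Other mitochondrial tRNAs fell with it in the MEFs. Of 22 tested, 13 fell and 0 rose in the mean of the Cl lines. mt-tRNA-Phe fell most after Ala, by a log2 change of -1.25 (SE 0.09, edgeR adjusted p = 8.22e-05). mt-tRNA-Leu-TAG (-0.97), mt-tRNA-Asp (-0.88), mt-tRNA-Trp (-0.87), mt-tRNA-Thr (-0.76), mt-tRNA-Ile (-0.72), mt-tRNA-Met (-0.70), mt-tRNA-His (-0.68), mt-tRNA-Arg (-0.68), mt-tRNA-Val (-0.67) and mt-tRNA-Leu-TAA (-0.63) fell as well. Without replicate 1 of Ctrl_1, Asp (-0.84, edgeR adjusted p = 0.0706) and Val (-0.52, edgeR adjusted p = 0.153) missed the threshold. mt-tRNA-Tyr fell by 0.39 on the log2 scale. Scaled on the other mitochondrial tRNAs, which removes a common fall, only Phe (-0.71) and Leu-TAG (-0.44) of these 12 stayed past the threshold, 9 missed it and Tyr was at 0.15. Calls under this scaling come from a fit that kept the nuclear rows.

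The fall followed the strand of the mitochondrial genome. Of the 14 mitochondrial tRNAs on the strand opposite to mt-tRNA-Ala, 11 fell, with a median log2 change of -0.74; adjusted over the list alone, 12 did. Of the 7 others encoded on its own strand, 1 fell, Tyr, also adjusted over the list alone, and the median was 0.02. mt-tRNA-Glu was at 0.60 and mt-tRNA-Asn at 0.40, neither past the threshold. The difference of the medians was 0.76 (exact permutation test over 116280 assignments of tRNAs to strands, two-sided p = 7.22e-04; tRNAs are not independent replicates). The strand lists were fixed before the data were examined, and this test of their difference was chosen after. Scaled on the other mitochondrial tRNAs, the medians were -0.21 and 0.54, so the direction of the strand of mt-tRNA-Ala depends on the scaling; a scaling shifts both medians together and so does not bear on their difference. Among the fixed lists, the mitochondrial tRNAs without Ala (camera with a preset correlation, adjusted p = 0.00254) and those on the other strand (adjusted p = 1.27e-04) passed, and with an estimated correlation neither did (adjusted p = 0.978 for both). The strand of mt-tRNA-Ala had a camera adjusted p of 0.963, and its genomic neighbours Trp, Asn, Cys and Tyr, of which 2 fell, 0.821.

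**Figure D2:**
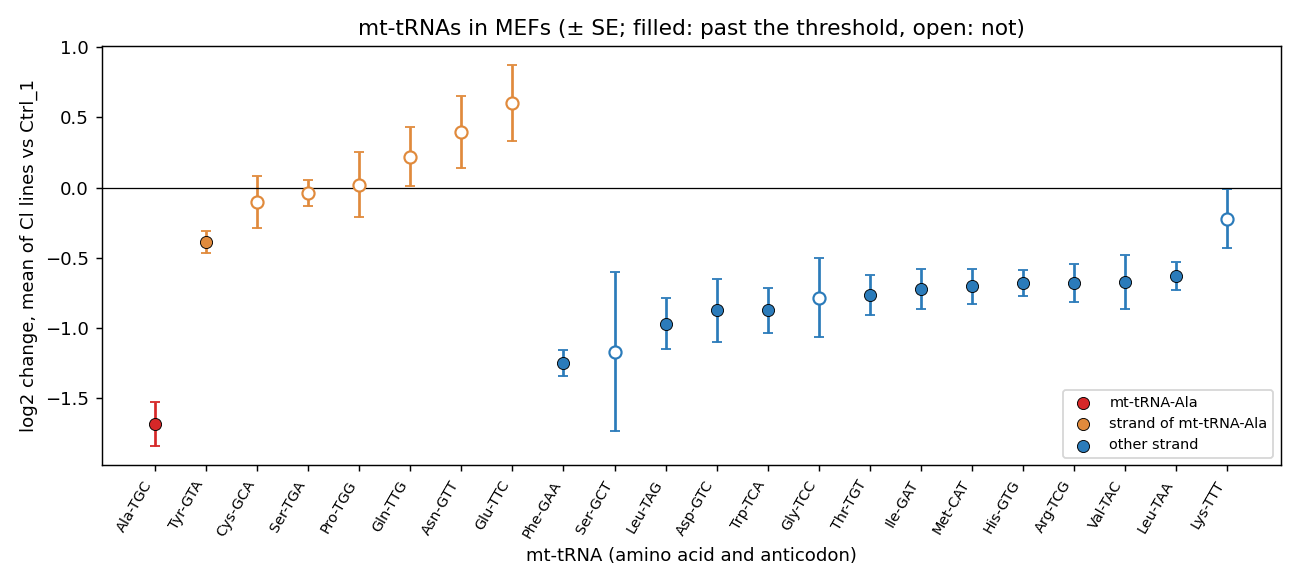
Log2 change (± SE) of each mitochondrial tRNA in the mean of the Cl lines against Ctrl_1, from edgeR on 8 MEF libraries, with mt-tRNA-Ala in red, the other tRNAs of its strand in orange and those of the opposite strand in blue; filled points passed the threshold. mt-tRNA-Ala (-1.68) and 11 of 14 tRNAs on the opposite strand are filled and below 0.

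Mitochondrial tRNAs took 2.54% ± 0.298 of all counts in the 6 Cl libraries and 3.57% ± 0.234 in the 2 Ctrl_1 libraries (SD; exact permutation test, two-sided p = 0.0357, the smallest that 28 splits allow; Benjamini-Hochberg adjusted p = 0.0714 over 4 share tests). mt-tRNA-Ala made up 0.691% ± 0.276 of mitochondrial tRNA counts in the Cl libraries and 1.38% ± 0.127 in Ctrl_1 (exact permutation test, two-sided p = 0.0357, Benjamini-Hochberg adjusted p = 0.0714). These splits take the 8 libraries as exchangeable although they are passages of 4 lines. With the lines as units, 3 against 1, the exact permutation p is 0.25 for both shares, the smallest that 4 splits allow; this test was added after the data were examined.

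Nuclear tRNAs, which serve cytosolic translation, moved in both directions in the MEFs: 46 of 175 rose and 38 fell in the mean of the Cl lines. tRNA-Asn-GTT-1 rose most among the named ones, from 25.9 ± 2.69 CPM in Ctrl_1 to 157 ± 27.5 in Cl_1, 365 ± 51.5 in Cl_2 and 492 ± 125 in Cl_3 (SD, n = 2 each), a mean log2 change of 3.56 (SE 0.24, edgeR adjusted p = 6.26e-05). tRNA-His-GTG-3 (2.39), tRNA-Gly-CCC-2 (1.83), tRNA-Ala-TGC-6 (1.83), tRNA-Cys-GCA-4 (1.54), tRNA-Gly-CCC-3 (1.38), tRNA-Arg-CCG-3 (0.93) and tRNA-Pro-TGG-1 (0.67) rose too. tRNA-Gln-CTG-4 fell from 25.6 ± 1.07 to between 3.63 and 7.05 CPM (log2 change -2.33, SE 0.14, edgeR adjusted p = 6.26e-05). tRNA-Leu-TAA-1 (-0.97), tRNA-Ser-GCT-2 (-0.67), tRNA-Lys-TTT-1 (-0.66), tRNA-His-GTG-2 (-0.60), tRNA-Val-TAC-1 (-0.41), tRNA-Glu-TTC-2 (-0.36) and tRNA-Pro-AGG-1 (-0.29) fell. Of 19 nuclear tRNA-Ala transcripts 5 rose, among them tRNA-Ala-TGC-5 (2.74), and 5 fell, among them tRNA-Ala-AGC-2 (-0.32), the same counts as adjusted over the list alone (camera adjusted p = 0.963). tRNA-Ala-TGC-5 lay near the floor, at 0.98 and 0.95 CPM in the Ctrl_1 libraries and 4.74 to 8.17 in the Cl libraries. The counts of members that share an anticodon depend on how near-identical reads were assigned: summed per anticodon, 11 of 48 nuclear anticodons rose and 7 fell.

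**Figure D3:**
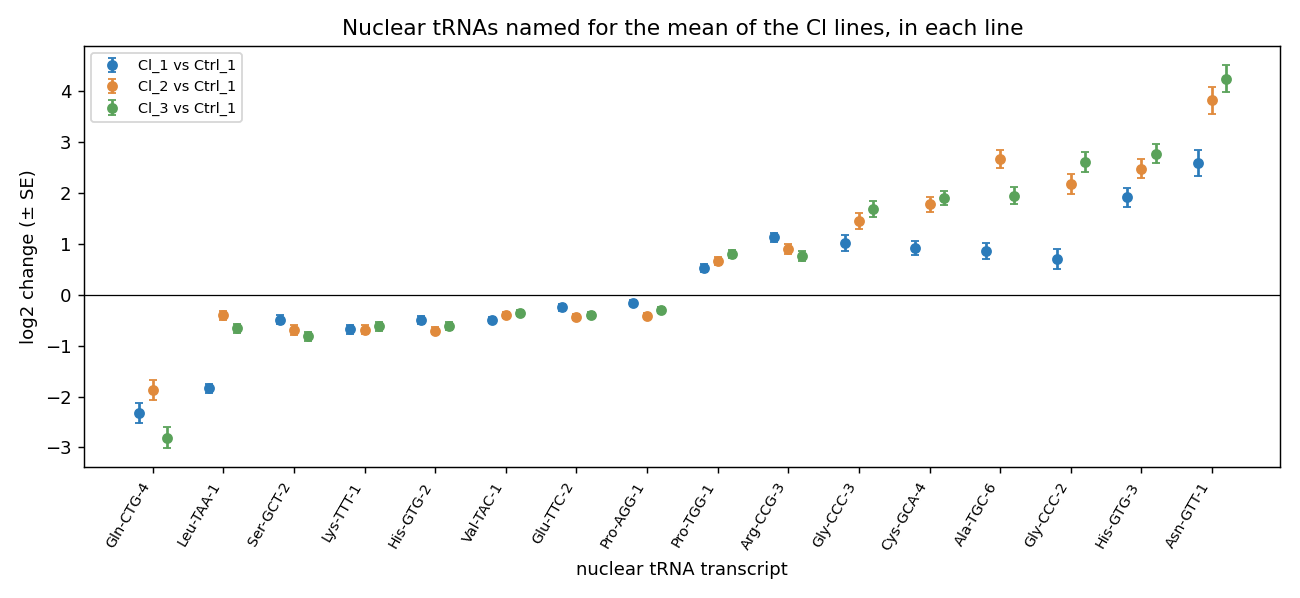
Log2 change (± SE) against Ctrl_1 of the 16 nuclear tRNA transcripts named for the mean of the Cl lines, shown for each Cl line. tRNA-Leu-TAA-1 is lowest in Cl_1 (-1.84), and tRNA-Asn-GTT-1 lies between 2.60 and 4.25.

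In total 97 of 201 transcripts passed the threshold in the mean of the Cl lines, 46 higher and 51 lower (edgeR). Cl_1 gave 30 higher and 38 lower, Cl_2 gave 52 and 41, and Cl_3 gave 53 and 49. In all 3 lines 22 transcripts rose and 23 fell, against 2.05 and 1.89 for independent lists and a mean of 0.02 in 50 simulations of unchanged lines against the shared control. The lines share their control libraries, too few to split, so part of the excess may come from them. A trait of the 1 control line would show in all 3 comparisons and is covered by neither baseline. The excess therefore cannot tell such a trait from a change in the Cl lines. Scaled on library totals, the split for the mean of the Cl lines was 61 higher and 35 lower, and on nuclear counts 40 higher and 60 lower, so the balance depends on the scaling. Without replicate 1 of Ctrl_1, 59 transcripts passed, and with the libraries of each line summed 9 did.

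Between the Cl lines, 49 transcripts differed (edgeR F test), and 19 to 40 when 1 library was left out. tRNA-Leu-TAA-1 was 1.43 lower on the log2 scale in Cl_1 than in Cl_2 and 1.18 lower than in Cl_3, as its changes against Ctrl_1 of -1.84, -0.40 and -0.66 show (F test, edgeR adjusted p = 3.03e-04). tRNA-Ala-TGC-6 rose by 0.86 in Cl_1, 2.67 in Cl_2 and 1.94 in Cl_3, and tRNA-Gly-CCC-2 by 0.70, 2.18 and 2.61. Cl_2 and Cl_3 differed in 2 transcripts, Cl_1 and Cl_2 in 34, and Cl_1 and Cl_3 in 52. Summed per anticodon, 1 of 74 values differed between the lines.

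In the hearts, mt-tRNA-Ala was higher after AAV9-DdCBE than after AAV9-GFP, without passing the threshold: 4025 ± 2026 against 1626 ± 549.7 CPM (SD, n = 4 each), a log2 difference of 1.31 (SE 0.39, edgeR adjusted p = 0.0866). It made up 0.879% ± 0.295 of mitochondrial tRNA counts after AAV9-DdCBE and 0.394% ± 0.141 after AAV9-GFP (SD, n = 4 each; exact permutation test, two-sided p = 0.0571, Benjamini-Hochberg adjusted p = 0.0762; the smallest p that 70 splits allow is 0.0286). By heart, the share was 0.202%, 0.409%, 0.428% and 0.539% in AAV9-GFP and 0.450%, 0.921%, 1.05% and 1.10% in AAV9-DdCBE. The hearts of mice 17 and 18, the highest, carry the label 10X in their titles, which give no explanation of it; mouse 26, the lowest of the AAV9-DdCBE hearts, carries 2X. In AAV9-GFP the lower 2 values belong to hearts labelled 3X and the higher 2 to hearts labelled 5X, so the share was ordered by the label in both treatments, with 1 or 2 hearts per label. Without mouse 26 the log2 difference was 1.68 (edgeR adjusted p = 0.0146), and the DESeq2 test gave 1.46 (DESeq2 adjusted p = 0.0132). Over 19 alternatives the log2 difference was 0.82 to 1.68 and the adjusted p 0.0132 to 0.407, and 3 passed the threshold. The alternative with only 5X hearts is not counted there, since it sets 1 AAV9-DdCBE heart against 2 (0.86, edgeR adjusted p = 1.26e-04), so that only the AAV9-GFP hearts give a spread.

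No transcript passed the threshold between AAV9-DdCBE and AAV9-GFP in edgeR (0 of 180; 35 at an unadjusted p under 0.05), while DESeq2 called 27, all higher, and edgeR on library totals 14. The transcripts with the smallest p, none past the threshold, were nuclear: tRNA-Ala-AGC-5 (log2 difference 3.70, SE 0.73), tRNA-Gly-CCC-2 (4.397, SE 0.95), tRNA-Cys-GCA-4 (4.78, SE 1.11), tRNA-Met-CAT-4 (3.69, SE 0.88) and tRNA-Val-CAC-1 (2.96, SE 0.75), each with an edgeR adjusted p of 0.0775. All 5 passed without mouse 26 (edgeR adjusted p 0.0106 to 0.0146) and without mouse 25 (edgeR adjusted p = 0.0331). Without mouse 17, labelled 10X, they were lower: 3.26, 3.79, 3.65, 3.04 and 2.22 in the same order. None of the 21 other mitochondrial tRNAs and none of 16 nuclear tRNA-Ala transcripts passed; adjusted over the list alone, 2 nuclear tRNA-Ala transcripts did. None of the 27 lists passed (camera adjusted p 0.529 and above). The strand medians were -0.10 and 0.06 (exact permutation test over tRNAs, two-sided p = 0.232). Mitochondrial tRNAs took 45.6% ± 9.87 of counts after AAV9-DdCBE and 40.3% ± 3.02 after AAV9-GFP (SD, n = 4 each; exact permutation test, two-sided p = 0.400), with mouse 17 at 59.9%; without that mouse the difference was 0.517 points.

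Because the AAV9-DdCBE hearts differed among themselves along the X label, a split of these hearts by that label was added after the comparison of 4 with 4 had called 0 transcripts. It gave 4 comparisons, each adjusted on its own: 10X, 5X and 2X against AAV9-GFP, and 10X against the others. In the 2 hearts labelled 10X, 43 transcripts were higher than in the 4 AAV9-GFP hearts and 50 lower (edgeR, 180 tested). mt-tRNA-Ala rose by 1.75 on the log2 scale, or 3.36-fold (SE 0.32, edgeR adjusted p = 0.00311), and mt-tRNA-Ile by 0.87 (SE 0.27, edgeR adjusted p = 0.0256). Without mouse 17, mt-tRNA-Ile was at 0.38 and missed the threshold (edgeR adjusted p = 0.234), and mt-tRNA-Ala was at 1.41 (edgeR adjusted p = 0.0733). The other 41 that rose were nuclear transcripts that were rare in AAV9-GFP hearts, and 36 of them rose more than 2-fold. tRNA-Cys-GCA-4 rose 52.8-fold, from 15.4 ± 2.96 (SD, n = 4) to 813 ± 427.5 (SD, n = 2) CPM. Its log2 change of 5.72 was 5.05 without mouse 17 and 6.19 without mouse 18. tRNA-Gly-CCC-2 rose 39.1-fold (log2 5.29, SE 0.22, edgeR adjusted p = 8.01e-07). tRNA-Met-CAT-4 (23.8-fold), tRNA-Val-AAC-4 (18.6-fold), tRNA-Val-CAC-1 (13.9-fold), tRNA-Ala-AGC-10 (11.4-fold), tRNA-Val-AAC-3 (10.2-fold) and tRNA-Val-AAC-2 (8.63-fold) rose too. Of 9 nuclear tRNA-Val transcripts 6 rose, of 7 tRNA-Cys transcripts 4, and of 16 tRNA-Ala transcripts 5, while 4 tRNA-Ala transcripts fell.

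tRNA-Arg-CCT-4 (-0.94), tRNA-Thr-AGT-2 (-0.82), tRNA-Met-CAT-1 (-0.80), tRNA-Ser-CGA-1 (-0.79), tRNA-Arg-CCG-3 (-0.77), tRNA-Ser-TGA-1 (-0.76), tRNA-Trp-CCA-2 (-0.75) and tRNA-Arg-TCG-2 (-0.69) were lower in the 10X hearts. Of these falls 7, all but that of tRNA-Arg-CCT-4, missed the threshold without mouse 6 of AAV9-GFP (log2 -0.64 to -0.55, edgeR adjusted p 0.0642 to 0.0734). Without mouse 5 of AAV9-GFP 5 did (log2 -0.61 to -0.50, edgeR adjusted p 0.0513 to 0.0764). The median log2 change of all tested transcripts was -0.23 under this scaling and -0.04 with DESeq2 size factors, where the split was 49 higher and 15 lower; all 41 nuclear rises stayed called there, and 15 of the 50 falls. Summed per anticodon, no value passed (0 of 70 in edgeR; 15 at an unadjusted p under 0.05), and mt-tRNA-Ala was at 2.15 (edgeR adjusted p = 0.0972). Without mouse 17, which leaves 1 heart labelled 10X, 41 transcripts passed, 29 higher and 12 lower. Without mouse 6 43 were higher and 2 lower, and without mouse 5 46 and 4, so the rises stayed while nearly all falls lost the call when either control heart was left out. Among the lists, camera called 0 of 27 (lowest adjusted p 0.296).

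The labels 5X and 2X were each carried by 1 AAV9-DdCBE heart, which has no spread of its own and is assumed to vary like the other groups, so calls for either carry no weight. Against AAV9-GFP, edgeR called 1 transcript in the 5X heart, tRNA-Gly-CCC-2 (log2 2.13), and 0 in the 2X heart (2 at an unadjusted p under 0.05). mt-tRNA-Ala was at 1.06 in the 5X heart and 0.12 in the 2X heart. The 10X hearts differed from the 5X and 2X hearts in 56 transcripts. mt-tRNA-Ala was not among them (log2 difference 1.16, SE 0.39, edgeR adjusted p = 0.0536). The label 10X was carried by AAV9-DdCBE hearts only, so against AAV9-GFP it cannot be separated from the editor. The comparison with the 5X and 2X hearts is within the editor. It takes each of these 2 hearts as a group of 1, so the difference between them adds nothing to the spread. The calls of that comparison are therefore under the same limit.

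**Figure D4:**
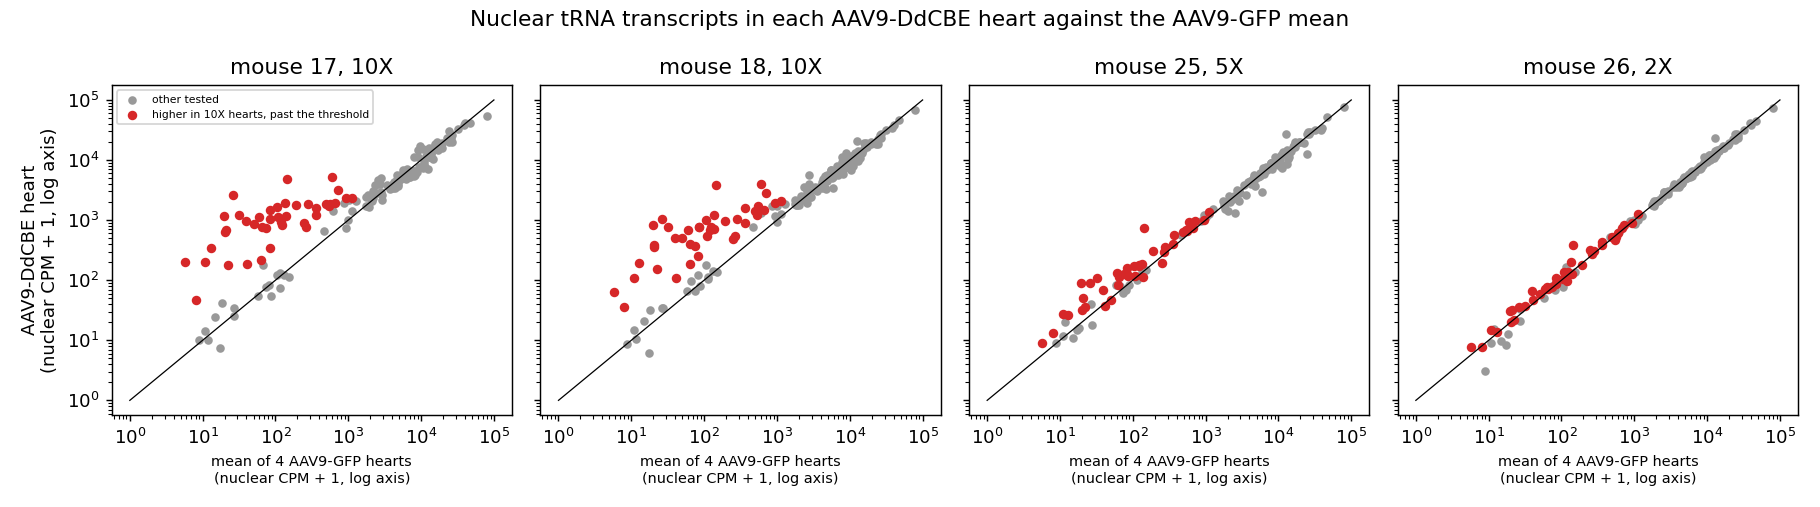
Each tested nuclear tRNA transcript in 1 AAV9-DdCBE heart (y axis) against the mean of 4 AAV9-GFP hearts (x axis), in CPM of nuclear tRNA counts plus 1, on log axes, with the line of equal values. The 41 nuclear transcripts in red were picked for being called higher in the hearts of mice 17 and 18 (10X), so their place above the line there follows from that choice.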

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

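The tests between the Cl lines were fixed before the data were examined. Scaling on the other mitochondrial tRNAs and summing the libraries of a line were planned as alternatives, but their use as tests of an explanation was chosen after their values were seen.

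The 3 Cl lines differed from each other, by the edgeR F test of the difference itself, in 20 of 44 named transcripts. Over all tested transcripts 49 of 201 differed. The 44 were named from the mean and from each single line against Ctrl_1, which favours transcripts extreme in 1 line. The adjusted p was 3.03e-04 for tRNA-Leu-TAA-1, 7.55e-04 for tRNA-Ala-AGC-3 and tRNA-Lys-TTT-2, 0.00113 for tRNA-Ala-TGC-6 and tRNA-Ala-AGC-10, 0.00143 for tRNA-Gly-CCC-2 and 0.00532 for tRNA-Phe-GAA-2. It was 0.00646 for tRNA-Cys-GCA-4, 0.00679 for tRNA-Asn-GTT-1, 0.00824 for tRNA-Leu-TAA-2, 0.0121 for tRNA-Gln-TTG-1, 0.0143 for mt-tRNA-Ala, 0.0172 for tRNA-Thr-TGT-3/2 and 0.0266 for tRNA-His-GTG-3. It was 0.0401 for tRNA-Ser-CGA-2, 0.0425 for tRNA-Gly-CCC-3, 0.0430 for tRNA-Pro-AGG-1, tRNA-Ala-AGC-2 and tRNA-Arg-TCT-4, and 0.0450 for tRNA-Trp-CCA-5.

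For the lower mt-tRNA-Ala of the Cl lines, less mitochondrial tRNA in those libraries is argued against as the whole cause: scaled on the other mitochondrial tRNAs the log2 change was still -1.14 (SE 0.14, edgeR adjusted p = 3.84e-07). By line it was -1.37 in Cl_1, -1.57 in Cl_3 and -0.48 in Cl_2 (edgeR adjusted p = 0.0323). That fit kept the nuclear rows, which entered the spread estimate and the adjustment. Its adjusted p-values are therefore not comparable with those of the main fit. The share of mt-tRNA-Ala in mitochondrial tRNA counts, which needs no fit, was 0.691% in the Cl libraries and 1.38% in Ctrl_1. Of the other mitochondrial tRNAs used for scaling, 14 lie on the opposite strand and 7 on the strand of mt-tRNA-Ala. Their median log2 changes in Cl_2 were -0.69 and -0.13. How much of the fall in Cl_2 goes with less mitochondrial tRNA therefore depends on the strand taken as reference. A trait of the 1 control line stays open because no second control line exists in these data; with 1 library per line the log2 change was -1.60 (edgeR adjusted p = 0.105), and neither value could have closed it. A sequence difference in the gene that alters how its reads align, and a biological effect of the mutation or of its editing, may also account for it and were not tested.

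Among 44 checks for a heart far from the others of its group, 2 stood apart, about what chance gives at 1 in 20. In AAV9-GFP, mouse 14 was set apart for tRNA-Met-CAT-1 (gap over range 0.961) and mouse 6 for tRNA-Arg-TCG-2 (0.869).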

How the results depend on the processing

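All values of mt-tRNA-Ala in the MEF comparisons with Ctrl_1 stayed below 0 in 72 of 72 alternatives (log2 -2.34 to -0.48). These are 18 settings each for the mean and the 3 lines, all against the same Ctrl_1 libraries, so the 72 values are not independent. With the libraries of a line summed, its mean change was -1.60 (adjusted p = 0.105) and 9 transcripts passed, from 3 lines against 1. With only the lines compared, Cl_1 gave 41 transcripts. Summed per anticodon, which leaves 74 tests, 29 passed for the mean of the Cl lines, 17, 26 and 20 for Cl_1, Cl_2 and Cl_3, and 1 between the lines. On library totals the splits were 54 higher and 25 lower for Cl_2 and 70 and 30 for Cl_3; on nuclear counts Cl_2 gave 40 and 49. Scaled on the other mitochondrial tRNAs, mt-tRNA-Tyr turned to 0.15 in the mean, 0.0227 in Cl_1, 0.24 in Cl_2 and 0.19 in Cl_3, as that scaling removes the common fall. The replicate numbers were not taken to pair the MEF libraries, since not every pair of lines deviated together (correlations 0.03 to 0.25, 4 of 6 above 0.1), though Ctrl_1, Cl_2 and Cl_3 did so weakly (0.16 to 0.25); with a replicate block 105 transcripts passed for the mean, and mt-tRNA-Ala was at -1.68.

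In the hearts, AAV9-DdCBE against AAV9-GFP gave 14 transcripts and 1.39 for mt-tRNA-Ala on library totals, 27 and 1.46 with DESeq2, and 46 and 0.86 with only 5X hearts, where 1 editor heart stands against 2 and has no spread of its own, so these calls carry no weight; with the X label as a covariate 1 passed. The cause was not tested. In the 10X hearts 57 passed on library totals (48 higher, 9 lower), 41 with at least 100 counts in every library (fewer transcripts tested) and 0 summed per anticodon, where mt-tRNA-Ala was at 2.15; on nuclear counts the split was 54 and 14. The comparison by X label and the library axis were chosen after seeing the data.

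Leaving out each library gave 59 to 101 transcripts for the mean of the Cl lines, 43 to 63 for Cl_1, 53 to 99 for Cl_2, 57 to 106 for Cl_3 and 19 to 40 between the lines; the counts against Ctrl_1 lay more than 1.5 times lower without replicate 1 of Ctrl_1 (59, 43, 54, 66). So did Cl_2 without its replicate 1 (53) and Cl_3 without its replicate 2 (57). The count between the lines was 31 without replicate 1 of Cl_1, 27 and 32 without replicate 1 or 2 of Cl_2, and 19 without replicate 2 of Cl_3. The DESeq2 test between the lines was not run. mt-tRNA-Ala in Cl_2 ranged from -1.16 to -0.82. A lone library is assumed to vary like the other groups. The share difference ranged from -1.20 to -0.865 points for mitochondrial tRNA and from -0.777 to -0.596 for mt-tRNA-Ala in the MEFs; without a Ctrl_1 library no exact p can pass (p = 0.143). In the hearts the range was 0 to 31 transcripts (31 without mouse 26, 19 without mouse 25), 0.96 to 1.68 for mt-tRNA-Ala and 0.411 to 0.627 points for its share. In the 10X hearts it was 41 to 121 transcripts (41 without mouse 17, 45 without mouse 6, 50 without mouse 5) and 1.41 to 2.06 for mt-tRNA-Ala. Of 2211 values of single transcripts and list medians, 2020 kept direction and side of the threshold, 156 lost the call, 29 gained one, 4 turned sign and 2 medians moved.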

Other observations

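All tests in this part were chosen after the results were seen, except the DESeq2 count over other splits, which was added once its count for the real split was known but before those of the others were.

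Some abundant nuclear tRNAs also set hearts apart. The mean log2 level of 6 of them (tRNA-Asp-GTC, tRNA-Glu-TTC, tRNA-Val-AAC, tRNA-Val-CAC and tRNA-Leu-CAG transcripts) was 12.2 in mouse 14, 12.4 in mouse 25 and 12.5 in mouse 18, against 12.9 to 13.2 in the others, and did not separate the treatments (exact permutation test, two-sided p = 0.486). These 6 were picked after the data were examined and do not stand for abundant nuclear tRNAs in general. For example, tRNA-Ile-AAT-1 was highest in mice 14 and 25, at 51871 and 51655 CPM of nuclear counts, against 40787 to 46444 in the others. tRNA-Ala-AGC-4 was at 8901 to 9575 CPM of nuclear counts in mice 6, 14 and 19 and at 15612 to 26727 in mice 5, 17, 18, 25 and 26. The 41 nuclear transcripts called higher in the 10X hearts took 5.58% and 3.94% of nuclear counts in mice 17 and 18, and 0.734% to 1.27% in the other 6 hearts, with 1.23% in the 5X heart and 0.981% in the 2X heart.

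With edgeR, the real split of the 8 hearts into 4 and 4 gave 0 transcripts, which all 35 splits meet by construction, so that count decides nothing. The highest other split gave 51 and set mice 14, 17, 18 and 25 against the rest, which points to a structure of the samples. These are the hearts lowest in the mean level of abundant nuclear tRNAs given above (12.2 to 12.9, against 13.1 to 13.2 in the rest). Both 10X hearts are among them, with mouse 14 of AAV9-GFP and mouse 25, labelled 5X, so the split does not tell the label from that level. With DESeq2 the real split gave 27 and 3 of 35 splits gave as many, the highest other 67, so chance cannot be excluded.

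The rise of rare nuclear tRNAs in the 10X hearts covers 41 transcripts, all below the median nuclear level in AAV9-GFP hearts. On nuclear counts 41 of 41 were still called higher. They had been picked under the scaling with the lowest median log2 change, -0.23 against 0.05 on nuclear counts, so keeping the calls decides nothing. A scaling shifts all transcripts of a library together, and these medians lie far from a 2-fold change. Scaling is therefore argued against as the whole cause of the 36 rises above 2-fold, and stays open for the smaller ones. Reads moved between near-identical transcripts of 1 anticodon, by assignment or by sequence errors, are a candidate explanation that stays open: within the 22 anticodons that hold a risen transcript, the gain of the risen members and the change of the rest had a Spearman rho of -0.359 (permutation p = 0.103; anticodons are not independent replicates), and -0.393 over all 47 (permutation p = 0.00722), where those without a risen transcript have a gain of 0 by construction. In percent of the anticodon total the median gain in these 22 was 6.99%, the median change of the rest -6.51% (-0.932% in anticodons without a risen transcript) and of the total -0.309%, which goes with moved reads, but shares of a fixed total lean the same way. Gain and rest were 22.5% and -22.6% in Val-AAC, 15.2% and 7.67% in Cys-GCA, and 29.2% and 29.0% in Ala-AGC, where tRNA-Ala-AGC-4, uneven between hearts as given above, made up most of the rise of the rest; the SD of these totals across AAV9-GFP hearts was 23.4%, 14.0% and 21.1%. An effect of the editor or of whatever 10X stands for stays open and untested, with 2 hearts.

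For the higher mt-tRNA-Ala in the 10X hearts, more mitochondrial tRNA in those libraries is argued against as the whole cause, since scaled on the other mitochondrial tRNAs it was 1.55 (SE 0.38, edgeR adjusted p = 0.00554). Nuclear rows stayed in that fit as well, so its adjusted p is not comparable with that of the main fit. With the library axis, the mean level of the picked nuclear tRNAs given above, as a covariate the value was 2.07 (SE 0.14, edgeR adjusted p = 4.11e-09). That fit cannot decide whether the axis accounts for the rise. Among AAV9-GFP hearts its slope rests on mouse 14, at 12.2 against 13.2 in the others and lowest in mt-tRNA-Ala (852 CPM). The hearts labelled 5X and 2X, each its own group, add nothing to the slope. Between all AAV9-DdCBE and all AAV9-GFP hearts the covariate gave 1.55 (edgeR adjusted p = 0.164). What the X label stands for, and reads that align differently after a base change, may also account for the higher mt-tRNA-Ala and were not tested.

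A hypothesis is that the nuclear transcripts higher in the 10X hearts are those higher in the Cl lines. Over 154 shared nuclear transcripts the log2 changes correlated (Spearman rho = 0.347, permutation p = 2.00e-05; transcripts are not independent replicates). Permuted within 5 bins of abundance the mean rho was 0.246 and p = 0.0432, so most of the relation goes with abundance. Of these, 40 rose in the 10X hearts and 41 in the Cl lines, 17 in both (10.6 if the lists were independent, which leaves abundance out of account), tRNA-Asn-GTT-1, tRNA-His-GTG-3, tRNA-Cys-GCA-4 and tRNA-Gly-CCC-2 among them. A common low-level read assignment may contribute, and was not tested separately.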
